A study of Mus with 8 samples.

How the data were processed

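Total RNA from mouse skin and hair follicle was labelled as biotinylated cRNA from 9.4 µg, per the labels' protocols, and hybridised to HT_MG-430_PM arrays, per the file headers. Affymetrix Expression Console, RMA and Transcriptome Analysis Console were used, per the submitters' processing notes, without versions. The deposited value table holds linear intensity for 45141 probesets in 8 arrays. Its background correction and between-array normalization are not given in the sources used here. Array medians were 35.9 to 37.7, and the lowest values, 13.8 to 22.5, leave an additive background, so differences of dim genes are understated. The authors' deposited comparison tables, 6 in all, hold log2 values per condition and a signed fold change, a score that is negative where the condition is lower. One of these tables also holds p-values, deposited as 1 in every row, since 1 array stands on each side.

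The tables were set against the value table. Log2 differences of the value table were 0.366 to 0.398 times those of the authors' deposited tables for the number 2 arrays, with r = 0.912 to 0.924 across probesets. For the number 1 arrays these slopes were 0.132 to 0.165 and r was 0.586 to 0.688. The sign was the same for 76.9% to 89.1% of listed probesets in the number 1 tables and for 99.9% in the number 2 tables. Control columns followed untreated array 1 at a Spearman rho of 0.412 to 0.471, and untreated array 2 at 0.905 to 0.935. The table that is named for minoxidil array 1 carries microsphere columns and repeats all 9387 rows of the microsphere table for number 1, so no authors' values for minoxidil array 1 were used. Values from the authors' tables and from the value table are on different scales and are named separately. For the number 1 arrays they differ in more than scale.

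Gene names came from the authors' tables, which list 28918 of the probesets: 23804 with 1 symbol, 844 with several and 4270 without. The remaining probesets are unnamed here. These tables keep probesets past a fold of 1.30 or 2.00 in these same samples, so the named set is not independent of the data. Of the genes tested, 10550 matched a current symbol and 378 a synonym in the RefSeq gene table of assembly GRCm38.p6, which was used only for names. No coordinates are given, because no file names a genome build.

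Values were put on the log2 scale, since the table proved to be linear. For each gene the probeset with the highest mean over the 8 arrays was kept, and genes at or above the 25th percentile of the mean were tested, leaving 11235. Because the files name only part of the probesets, the test of every probeset was kept as an alternative. The fit used limma 3.58.1 in R 4.3.3 with 4 group means, lmFit and eBayes with an intensity trend, 4 residual degrees of freedom and Benjamini-Hochberg adjustment, with a threshold of 0.05. With 2 arrays against 2, an exact permutation test cannot go below a two-sided p of 0.333, so none was used. Gene lists, 32 fixed before the data were examined, were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists of a comparison. Older symbols of list members were matched through synonyms. Named genes were, per comparison, up to 10 in each direction with arrays of the groups not overlapping, first those past the threshold and then those at an unadjusted p below 0.01. Up to 4 members of a list with the largest differences, and 6 genes fixed for minoxidil, were added, and predicted genes were skipped.

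The fit and the list test were tested on simulated data with 200 changed genes of known size. No 2 arrays held identical values. Alternatives covered scaling, filtering, probeset choice, the variance model, array weights, thresholds, the replicate number as a block, and each array left out. Alternatives chosen after seeing the data left out minoxidil array 1, left it out with the block, left out untreated array 1 as well, applied normexp background correction with offsets of 50 and 16, and left 6 genes that are not ribosomal proteins out of the ribosomal list. Similarity of treatment effects was set beside 50 simulated draws of unchanged groups. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.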

Results

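Skin with its hair follicles was taken from C57BL6 mice after 20 days of topical treatment, and its RNA was measured on 8 Affymetrix mouse arrays. The mice, in groups of 5 per the labels, received MilliQ water (called untreated here), 1% minoxidil, 1% keratin or 1% microsphere keratin. Minoxidil is a vasodilator used against hair loss and served as the positive control. Keratin is the structural protein of hair. Each group had 2 arrays, numbered 1 and 2 in the labels. The labels do not say whether these are separate animals, pools or repeat hybridisations, so p-values measure only the spread between the arrays, which may be technical. The number of arrays limits the precision.

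The arrays differed in quality. Minoxidil array 1 correlated with the other 7 arrays at r = 0.390 to 0.475 over all probesets, while those 7 correlated with each other at 0.886 to 0.988. Its 3′ beta-actin control probeset read 47.2, against 656 in untreated array 1 and 1449 to 1883 in the remaining 6 arrays. Its 3′ Gapdh probeset read 196, against 298 in untreated array 1 and 630 to 1605 in the rest. BioB, a bacterial transcript added at hybridisation, read 738 in untreated array 1 and 429 in minoxidil array 1, against 91.3 to 208 elsewhere. The median intensity over all probesets was nevertheless 35.9 to 37.7 in all 8 arrays. For most gene lists the difference is therefore also given within the number 1 and the number 2 arrays.

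**Figure D1:**
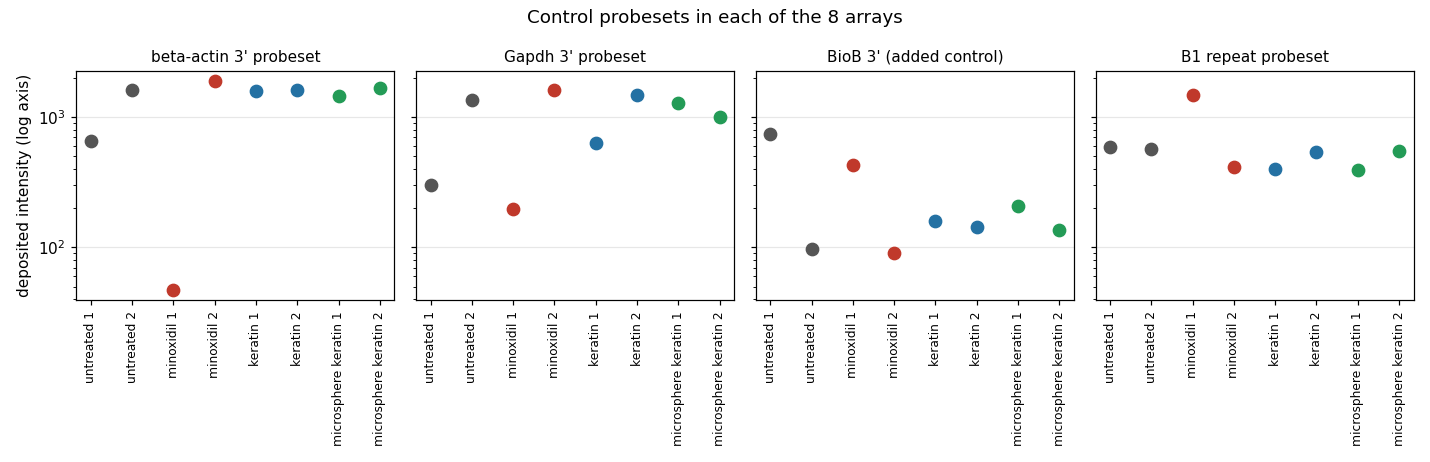
Deposited intensity (log axis) of 4 control probesets in each of the 8 arrays, 1 point per array, coloured by group. Minoxidil array 1 has the lowest beta-actin (47.2) and Gapdh (196) values and the highest B1 repeat value (1465), and untreated array 1 has the highest BioB value (738).

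No gene passed the test in any comparison. Of the 11235 genes tested with limma, 0 had a Benjamini-Hochberg adjusted p below 0.05 in each of the 6 pairwise comparisons, and 0 in the moderated F test for any difference among the 4 groups. An unadjusted p below 0.05 was reached by 50 genes for minoxidil, 46 for keratin and 10 for microsphere keratin against untreated. Evenly spread p-values would give 562. The fit pools the spread over all 4 groups. The SD of the log2 difference between a group's 2 arrays was 0.92 for minoxidil and 0.35 to 0.41 elsewhere. Such pooling can enlarge the p-values of comparisons without minoxidil, so the shortfall is not read as a result about the treatments. Simulated 2-fold changes of the keratin comparison, on the scale of the value table, were recovered for 33.0% of changed genes and 4-fold changes for 68.0%. For minoxidil against untreated the shares were 21.0% and 57.0%. Each comparison had a single draw over 11235 genes, with independent noise. The noise had the spread pooled over all 4 groups, minoxidil array 1 included. With no gene passing, the genes and gene lists named below are described by their values. The words "rose" and "fell" are used only of lists that passed camera at the preset correlation.

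The keratin comparison asked how skin treated with keratin differed from untreated skin. The clearest group was the keratin-associated proteins, which cross-link keratin filaments in the hair shaft. Of 35 measured members, 34 were higher in keratin-treated skin, 29 in both same-numbered pairs, and 23 with both keratin arrays above both untreated arrays. Over all genes tested the median log2 difference was 0.10. Of these genes, 54.8% had the same sign in both pairs and 25.2% did not overlap, in either direction. Krtap4-7 had a log2 value of 6.35 ± 0.26 (SD, n = 2) with keratin and 5.44 ± 0.04 (SD, n = 2) without, a 1.88-fold difference. Krtap5-1 had 6.36 ± 0.36 (SD, n = 2) and 5.45 ± 0.09 (SD, n = 2), a 1.89-fold difference. Krtap17-1 differed by 1.59 on the log2 scale in the number 1 pair and 1.13 in the number 2 pair. The mean of the list was 0.53 higher on the log2 scale in the number 1 pair and 0.43 higher in the number 2 pair. Over the 8 arrays, keratin arrays 1 and 2 ranked 1 and 2 for this mean. As a list the keratin-associated proteins rose (camera with the preset correlation of 0.01, adjusted p = 1.5e-20). The call was lost with the correlation estimated from the data, 0.366 for this list (adjusted p = 0.622). It was also lost without untreated array 2, where the mean difference was 0.36 (adjusted p = 0.434). The mean difference of 0.48 ran from 0.30 without keratin array 1 to 0.66 without keratin array 2. No member passed, either over all genes or adjusted over the list alone. Krtap5-1 and Krtap4-7 were the only genes of this comparison that met the naming rule below unadjusted p 0.01, and both had an adjusted p of 1.00 in limma. Near-identical copies within this family can share probes, so single members are uncertain.

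Other lists of the keratin comparison moved less evenly. The epidermal differentiation list rose (adjusted p = 0.0169, and 0.622 with an estimated correlation), with 21 of 23 members higher. Its largest differences were in Ivl (0.59 ± 0.36 SE), Krt1 (0.58 ± 0.26 SE), Sbsn and Krt10, genes of the keratinising epidermis. The macrophage and dendritic list rose (adjusted p = 3.2e-06, and 0.996 with an estimated correlation), led by the antigen-presentation genes H2-Aa, H2-Eb1, Cd74 and H2-Ab1 at 0.86 to 0.91. Its mean difference was 0.72 in the number 1 pair and 0.07 in the number 2 pair. Untreated array 1, the control of the number 1 pair, was low in beta-actin and Gapdh. Some uncalled lists had a like pattern in these pairs: skeletal muscle at 0.84 and 0.07, and sebaceous gland at 0.55 and -0.04. Endothelium was at 0.07 and -0.05. The dermal extracellular matrix list (adjusted p = 0.0498, and 0.996 with an estimated correlation) differed by 0.61 in the number 1 pair and -0.01 in the number 2 pair, and its call was lost with the replicate number as a block (adjusted p = 0.171). That call was also lost with array weights (adjusted p = 0.120), the median filter (0.0742), normexp at offsets 50 and 16 (0.0988 and 0.119) and without minoxidil array 2 (0.0645). Col1a1, a fibrillar collagen, differed by 1.10 ± 1.15 (SE). The interferon response list rose with 12 of 13 members higher (adjusted p = 0.0046, and 0.996 with an estimated correlation). Cell division and hair matrix regulators ranked below the other genes (adjusted p = 0.0105 and 0.0169, both 0.996 with an estimated correlation). Their mean differences were 0.02 and -0.02, while the median of all genes was 0.10. Both calls were lost with no filter on dim genes (adjusted p = 0.340 and 0.120) and with every probeset tested (0.211 and 0.0711). Quantile normalization ended the epidermal (adjusted p = 0.192) and extracellular matrix (0.104) calls, and the interferon call was lost with no filter (0.208) and with the median filter (0.0742). Without untreated array 2 all 7 list calls of this comparison were lost, at adjusted p from 0.434 to 0.917. Without keratin array 1 the keratin-associated proteins were still called up, the extracellular matrix list, at a mean of -0.01, ranked below the other genes (adjusted p = 0.0106) and the other 5 calls were lost. For the extracellular matrix list the untreated arrays had means of 6.18 and 6.17, and keratin arrays 1 and 2 had 6.78 and 6.16. For the macrophage list the same means were 5.76 and 5.76, and 6.48 and 5.83.

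Only 2 genes were at least 2-fold higher in both same-numbered keratin pairs, Krtap17-1 and Sqstm1, and 0 were lower. The crossed pairs gave 1. Sqstm1, an autophagy receptor, was singled out after its values were seen and differed by 1.20 ± 0.65 (SE) on the log2 scale.

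The minoxidil comparison was dominated by minoxidil array 1. The ribosomal protein list was 2.51 lower in the number 1 pair and 0.07 lower in the number 2 pair, and the skeletal muscle list was 2.26 lower and 0.24 higher. The ribosomal list was fixed by name prefix, and 6 of its 53 members are not ribosomal proteins: the kinases Rps6ka1, Rps6ka2, Rps6ka3, Rps6ka4 and Rps6kb1, and Rps19bp1. Without these 6, an alternative chosen after seeing the data, the pairs gave -2.76 and -0.08 (adjusted p = 1.6e-12, and 0.868 with an estimated correlation). Likewise 6 of the 72 oxidative phosphorylation members are Ndufaf assembly factors. Tnni2, a troponin subunit of fast muscle, read 21.4 and 1412 in minoxidil arrays 1 and 2 and 872 and 1391 in untreated arrays 1 and 2. With all 8 arrays, camera called ribosomal proteins (adjusted p = 4e-12), keratin-associated proteins, oxidative phosphorylation, skeletal muscle and heat shock genes down and sebaceous gland genes up. The number 1 and number 2 pairs gave -0.59 and 0.03 for keratin-associated proteins, -1.31 and 0.09 for oxidative phosphorylation, and -0.85 and 0.03 for heat shock genes. All 6 calls were lost at adjusted p = 0.868 with an estimated correlation. Without minoxidil array 1, skeletal muscle and oxidative phosphorylation turned upward, with mean differences of 1.41 and 0.70. Untreated array 1 was low for both, and without it as well the differences were 0.24 and 0.09, with both calls lost (adjusted p = 0.165 and 0.385). Without minoxidil array 1 alone, the ribosomal and heat shock calls were lost, at 0.17 (adjusted p = 0.217) and 0.27 (adjusted p = 0.821). The keratin-associated call was kept without minoxidil array 1, though the mean difference was then -0.088. It was lost without untreated array 1 and without minoxidil array 2. Without untreated array 2 the muscle (adjusted p = 0.554), oxidative phosphorylation (0.508) and heat shock (0.0807) calls were lost, the last also without untreated array 1 (0.0693). Quantile normalization and the median filter ended the muscle (adjusted p = 0.0787 and 0.0763) and heat shock (0.0914 and 0.166) calls.

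Sebaceous gland genes, which make the lipids of sebum, had a mean 0.67 higher in minoxidil array 2 than in untreated array 2, and 0.37 lower in the number 1 pair. Other lists were high in minoxidil array 2 too: relative to the mean of the 7 arrays other than minoxidil array 1, it lay at 0.90 for skeletal muscle, 0.52 for brown fat and 0.48 for sebaceous gland. Fa2h, a fatty acid hydroxylase, read 277 in minoxidil array 2 and 62.1 in untreated array 2. Elovl4, which lengthens very long fatty acids, read 234 and 56.8. In the authors' deposited table for these arrays, Sdr16c6 was 10.8-fold, Elovl4 9.10-fold, Fa2h 8.99-fold and Far2 8.20-fold higher. Sdr16c6 and Far2 were named after their values were seen. The sebaceous list call had an adjusted p of 0.0345 with all arrays and 3.2e-11 without minoxidil array 1, and 0.647 without that array and with an estimated correlation. Minoxidil array 2 is then the only array of its group, assumed to vary like the others. With all arrays the call was lost after quantile normalization (adjusted p = 0.117), with no filter (0.0864), with the median filter (0.124) and with normexp at offset 16 (0.0588). It was also lost without untreated array 2 (adjusted p = 0.508) and without minoxidil array 2 (0.658).

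Slc27a4, a fatty acid transporter, and Aadac, an esterase, met the naming rule without passing. Slc27a4 had a log2 value of 6.32 ± 0.24 (SD, n = 2) with minoxidil and 5.52 ± 0.17 (SD, n = 2) without. Aadac had 5.51 ± 0.03 (SD, n = 2) and 5.03 ± 0.16 (SD, n = 2). None of the 5 tested genes fixed beforehand for minoxidil passed the limma test. Sult1a1, the sulfotransferase that activates minoxidil, differed by 0.00 ± 0.38 (SE), Vegfa by 0.30 ± 0.25 (SE), Igf1 by 0.05 ± 0.33 (SE), Fgf7 by -0.20 ± 0.16 (SE) and the potassium channel subunit gene Abcc9 by -0.10 ± 0.75 (SE). Kcnj8 was not among the genes tested. With keratin the differences were 0.33, -0.04, 0.44, 0.22 and 0.13 in the same order, and with microsphere keratin 0.49, -0.02, 0.46, -0.14 and 0.13, each at a limma adjusted p of 1.00. No gene was 2-fold apart in both same-numbered minoxidil pairs, while the crossed pairs gave 12.

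Microsphere keratin against untreated skin gave lists that rested on the number 1 pair. The dermal extracellular matrix list rose (adjusted p = 0.0056, and 0.960 with an estimated correlation), with 32 of 35 members higher. Its mean difference was 0.63 in the number 1 pair and 0.08 in the number 2 pair, and the median of all genes was 0.10. Untreated array 1, the control of the number 1 pair, was low in beta-actin and Gapdh. In that pair uncalled lists were higher too. Skeletal muscle means were 9.39 with microsphere keratin and 7.36 without, oxidative phosphorylation 7.66 and 6.66, and endothelium 5.53 and 5.46. Col1a1 differed by 1.39 ± 1.15 (SE), and Sparc, a matrix glycoprotein, by 1.02 ± 1.36 (SE). The macrophage and dendritic list rose (adjusted p = 0.0056, and 0.960 with an estimated correlation), by 0.55 and 0.03 in the same pairs, with H2-Eb1 and Cd74 leading. The replicate number as a block ended both calls (adjusted p = 0.111 and 0.0792), as did quantile normalization (0.0572 for both) and array weights (0.0514 and 0.114). Both were also lost without untreated array 2 (adjusted p = 0.989) and without microsphere keratin array 1, where the means of 0.07 and 0.02 ranked below those of the other genes (adjusted p = 0.0425 for both). The macrophage call was lost without minoxidil array 2 as well (adjusted p = 0.0794). The naming rule gave no gene here. No gene was 2-fold apart in both same-numbered pairs, nor in the crossed pairs.

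Regulators of the hair matrix, the dividing cells at the base of the follicle, were highest in microsphere keratin array 2. Shh, a growth signal of the hair follicle, read 137 in that array and 42.2 in microsphere keratin array 1, against 51.6 and 46.0 in untreated arrays 1 and 2. Its difference was 0.64 ± 0.52 (SE). Gli1, a target of that signal, differed by 0.51 ± 0.33 (SE). In the authors' deposited table for the number 2 arrays, Shh was 5.58-fold higher.

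**Figure D2:**
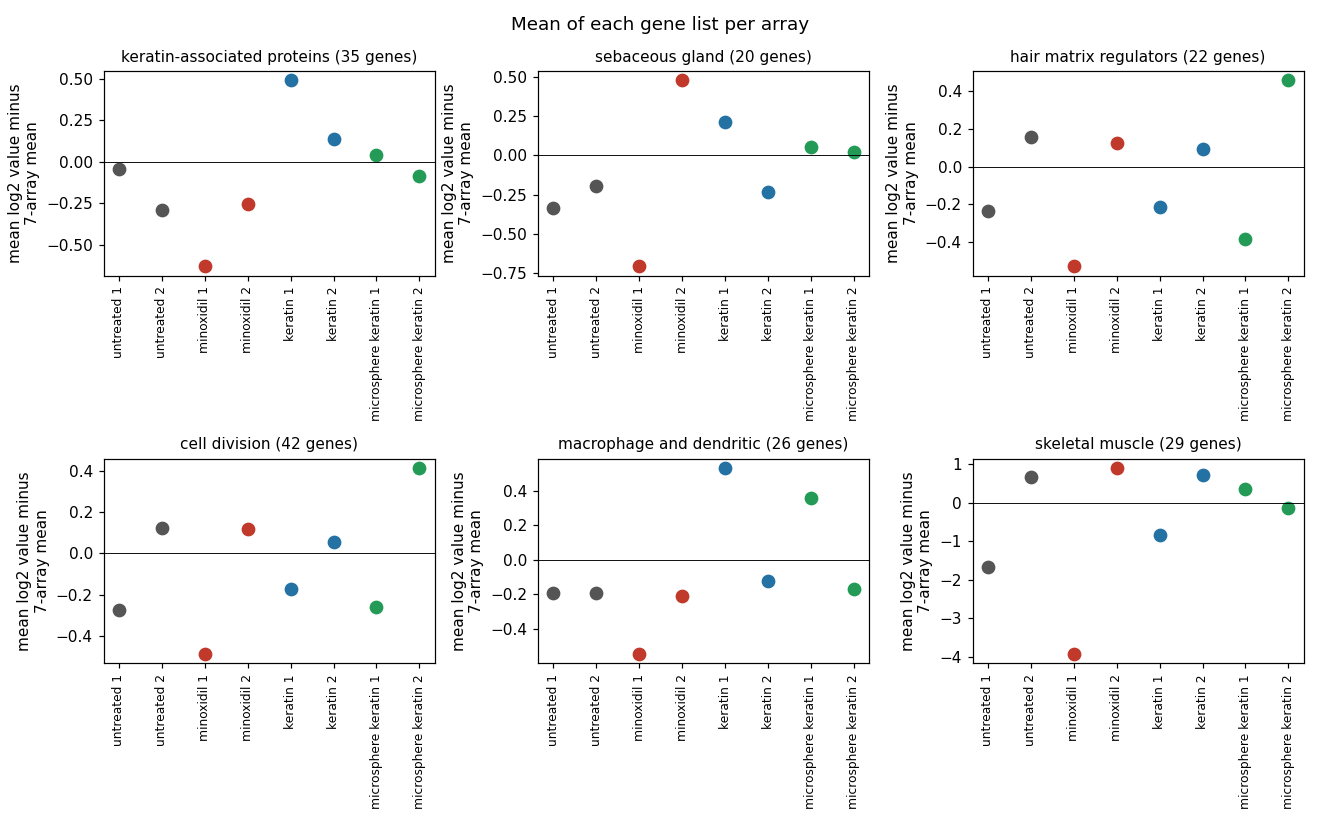
Mean log2 value of 6 gene lists in each of the 8 arrays, relative to the mean of the 7 arrays other than minoxidil array 1, with 1 point per array coloured by group. Keratin arrays 1 and 2 lie at 0.49 and 0.14 for keratin-associated proteins, minoxidil array 2 at 0.48 for sebaceous gland, and microsphere keratin array 2 at 0.46 for hair matrix regulators.

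Microsphere keratin was next set against keratin at the same concentration of 1%. Limma called 0 genes, with 14 at an unadjusted p below 0.05. The keratin-associated proteins fell (adjusted p = 1.9e-31, and 0.308 with an estimated correlation), with 34 of 35 members lower, 28 in both pairs. Over all genes tested the median difference was -0.011, and 40.8% had the same sign in both pairs. Krtap5-4 differed by -0.78 ± 0.31 (SE) and Krtap17-1 by -1.08 ± 0.78 (SE). The list was not below untreated skin: its means were 5.95 and 5.83 in microsphere keratin arrays 1 and 2. Those of untreated arrays 1 and 2 were 5.87 and 5.63. The epidermal differentiation list fell (adjusted p = 6.1e-08, and 0.125 with an estimated correlation), with 15 of 23 members lower in both pairs. Krt1 differed by -0.59 ± 0.26 (SE), and Krtdap, a marker of differentiating keratinocytes, by -0.47 ± 0.22 (SE). The cell division list rose (adjusted p = 2.2e-07, and 0.921 with an estimated correlation), by -0.09 in the number 1 pair and 0.36 in the number 2 pair, with Mcm5, Rrm2, Tyms and Mki67 leading. Without microsphere keratin array 2 it turned to -0.20 (adjusted p = 1.4e-04). Melanocyte genes were called up (adjusted p = 0.0019, and 0.421 with an estimated correlation), at -0.03 in the number 1 pair and 0.23 in the number 2 pair. That call was lost without microsphere keratin array 2 (adjusted p = 0.243) and without keratin array 2 (adjusted p = 0.451). Clock genes were called down (adjusted p = 0.0211, and 0.921 with an estimated correlation), at 0.09 and -0.26 in the same pairs, a call lost without either of those arrays and with the median filter (adjusted p = 0.225). Macrophage genes were called down (adjusted p = 0.0398, and 0.921 with an estimated correlation), at -0.18 and -0.05, and turned upward without keratin array 1 (0.21) or microsphere keratin array 2 (0.15). The macrophage call was also lost with no filter (adjusted p = 0.0621), with array weights (0.0929) and without either minoxidil array (0.0748 and 0.103). Dct, a melanin-synthesis enzyme, differed by 0.50 ± 0.34 (SE).

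Minoxidil was also set against both keratin preparations. Against keratin, 0 genes passed, with 125 at an unadjusted p below 0.05. Keratin-associated proteins were lower with minoxidil in 34 of 35 members, all 34 in both pairs, and 16 members passed adjusted over the list alone. Both counts include minoxidil array 1, with its weak signal, so the number 1 pair adds little to the number 2 pair. Over all genes tested the median difference was -0.12, and 44.0% had the same sign in both pairs. The list fell (adjusted p = 7.2e-23, and 0.669 with an estimated correlation), by 1.12 in the number 1 pair and 0.39 in the number 2 pair. Of the genes that met the naming rule, 7 were keratin-associated proteins and lower with minoxidil. They ran from Krtap6-5, at -1.31 ± 0.39 (SE), through Krtap5-4, Krtap4-16, Krtap3-3, Krtap4-7 and Krtap5-1 to Krtap5-2, at -0.59 ± 0.17 (SE). Without minoxidil array 1, Krtap6-5 differed by -0.97, Krtap5-4 by -0.75 and Krtap5-2 by -0.35. Pdss1, which makes the side chain of coenzyme Q, was 1.33-fold higher. All had an adjusted p of 0.928 in limma. In all, 6 lists were called down against keratin. The others were epidermal differentiation (adjusted p = 0.0193, and 0.669 with an estimated correlation), dermal extracellular matrix (0.0092), macrophage and dendritic (1.4e-06), ribosomal proteins (1.1e-08) and oxidative phosphorylation (0.0086), the last 4 at adjusted p = 0.922 with an estimated correlation. Ribosomal proteins differed by -3.12 in the number 1 pair and -0.05 in the number 2 pair, oxidative phosphorylation by -1.93 and 0.16, extracellular matrix by -1.36 and 0.18, macrophage genes by -1.08 and -0.09, and epidermal genes by -0.48 and -0.15. The block ended the extracellular matrix call (adjusted p = 0.0601). Without minoxidil array 2 the epidermal (adjusted p = 0.785), extracellular matrix (0.151) and macrophage (0.269) calls were lost, and likewise without keratin array 1 (0.221, 0.438 and 0.398). The epidermal call was also lost with quantile normalization (adjusted p = 0.234) and array weights (0.0591). Oxidative phosphorylation turned to 0.43 without minoxidil array 1 (adjusted p = 5.2e-07), and its call was lost without keratin array 2 (0.247), with the median filter (0.0886) and with normexp at offset 50 (0.0782).

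Against microsphere keratin, 0 genes passed, with 28 at an unadjusted p below 0.05. Keratin-associated proteins fell with 33 of 35 members lower (adjusted p = 3.4e-06, and 0.907 with an estimated correlation), at -0.67 in the number 1 pair and -0.16 in the number 2 pair. The median difference of all genes was -0.11. Skeletal muscle (adjusted p = 0.0033), extracellular matrix (6.1e-04), macrophage (2e-04), ribosomal (5.5e-10) and oxidative phosphorylation (2.4e-04) lists were also called down, each at adjusted p = 0.907 with an estimated correlation. Muscle differed by -4.29 in the number 1 pair and 1.05 in the number 2 pair, oxidative phosphorylation by -2.31 and 0.49, extracellular matrix by -1.38 and 0.10, macrophage genes by -0.90 and -0.04, and ribosomal proteins by -2.996 and -0.12. Minoxidil array 1, with its weak signal, is the minoxidil array of the number 1 pair. Without it, muscle turned to 0.80 (adjusted p = 5e-06) and oxidative phosphorylation to 0.40 (adjusted p = 7.6e-06). Without minoxidil array 2 the keratin-associated (adjusted p = 0.227), extracellular matrix (0.126) and macrophage (0.400) calls were lost. Without microsphere keratin array 1 the muscle (adjusted p = 0.321), extracellular matrix (0.734), macrophage (0.886) and oxidative phosphorylation (0.149) calls were lost. The median filter (adjusted p = 0.0775) and normexp at offset 50 (0.0677) also ended the muscle call. Leaving out minoxidil array 2, so that array 1 stands alone for its group, gave 860 genes against untreated, 1660 against keratin and 1467 against microsphere keratin.

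The 3 treatment effects share the untreated arrays. Across the 11235 genes, which are not independent replicates, the differences of keratin and microsphere keratin from untreated correlated at r = 0.745, against 0.497 for simulated unchanged groups. Their covariance was 0.0237, against 0.105 simulated. The simulated spread includes minoxidil array 1, which raises the simulated covariance. Every simulated group had the same spread per gene, which sets the simulated correlation near 0.50. In the data the SD of the log2 difference between a group's 2 arrays was 0.41 for untreated and 0.92 for minoxidil. It was 0.35 for both keratin preparations. The simulated correlations therefore cannot show whether the observed ones are high or low. The minoxidil differences correlated at -0.0485 with those of keratin and -0.0424 with those of microsphere keratin, each against 0.50 simulated. They include minoxidil array 1: its pair with untreated array 1 had 1202 genes at least 2-fold apart, against 32 in the number 2 pair. Both minoxidil correlations turned positive after quantile normalization (0.0819 and 0.120) and without either untreated array (0.338 to 0.351 and 0.371 to 0.374). With all arrays the covariances were -0.0033 and -0.0026, each against 0.105 simulated. Splitting the controls would leave 1 array on each side, so part of the similarity may come from the shared controls.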

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

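All tests in this part except that of probesets named for several genes were chosen after the result was seen. The B1 repeat control probeset, which takes no part in the gene tests, read 1465 in minoxidil array 1, above the highest untreated value of 592. The B2 repeat probeset read 3288 there, below untreated array 2 (3592) and microsphere keratin array 2 (3486). A further B2 probeset read 655, above the highest other value of 506.

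For minoxidil array 1, which stood apart from the other 7, the tables argue against a minoxidil effect shared by both minoxidil arrays: relative to the mean of those 7, the ribosomal list lay at -2.93 in array 1 but at -0.015 in array 2, within the -0.43 to 0.19 of the 6 arrays of other groups. Too little mouse RNA on the array is a candidate explanation, since its Gapdh reading was 0.656 times the lowest of the other 7 while the added BioB control was not lower. The Lys control was at its lowest there, at 89.1 against 158 to 741 elsewhere. The Dap control, at 1208, lay within the 929 to 2440 of the other arrays. These 2 controls do not separate little RNA from poor labelling. Genomic or repeat-derived nucleic acid may also contribute, though the repeat controls above went both ways. Probesets named for several genes made up 8 of the 61 listed probesets over 4 times brighter there, against 844 of 28888 listed (odds ratio 5.05, 95% interval 2.07 to 10.7, Fisher's exact test, p = 3.8e-04), and these last 2 explanations stay open, as does an untested effect in 1 minoxidil sample alone.

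Arrays numbered 1 differed from arrays numbered 2 in a similar way in several groups. Different amounts of target stay open: BioB was brighter in the number 1 array in 4 of 4 groups, as were BioC and Dap, but Lys in 3 and Cre in 2. Cre read 2518 and 2834 in keratin arrays 1 and 2, and 2777 and 2861 in microsphere keratin arrays 1 and 2. Muscle list means in arrays 1 and 2 were 7.36 and 9.69 for untreated, 8.20 and 9.76 for keratin and 5.10 and 9.94 for minoxidil. For microsphere keratin they ran the other way, 9.39 and 8.88, so array 1 was higher by 0.51 on the log2 scale. This lies within the SD of 1.65 for a difference between single arrays. That SD was built from such differences between numbers, minoxidil left out, so it cannot settle whether number 2 samples held more muscle. No explanation from the study's groups was tested, since the labels give the number no meaning.

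Hair matrix regulators were highest in microsphere keratin array 2. An effect of the treatment on both arrays was not settled. The list mean of microsphere keratin array 1 minus untreated array 1 was -0.15, within the SD of 0.57 for a difference between single arrays. That SD comes from number 1 against number 2 differences, the high microsphere keratin array 2 included. It therefore cannot judge a difference between arrays that are both numbered 1. The list was higher in the number 2 array in 4 of 4 groups, untreated included. Minoxidil array 1 and untreated array 1 were low in beta-actin and Gapdh, and the microsphere keratin group is the pattern itself. Only keratin, at 5.90 and 6.21 in arrays 1 and 2, is free of these limits. The count thus gives little support to a difference that goes with the array number, which stays open. An effect seen in 1 microsphere sample alone stays open and untested.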

How the results depend on the processing

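The alternatives that left out minoxidil array 1 alone or with untreated array 1, those that joined this to the block, both normexp corrections and the shorter ribosomal list, which changed no count of list calls, were chosen after seeing the data. Counts of changed genes stayed at 0 under every alternative except those named here. Leaving out 1 array at a time gave 0 to 860 genes for minoxidil against untreated, 0 to 1660 against keratin, 0 to 1467 against microsphere keratin and 0 to 163 in the F test. The high values arose without minoxidil array 2, where minoxidil array 1 alone stands for its group. At unadjusted p below 0.01 with a 2-fold minimum, 4 genes differed between minoxidil and keratin. Signal over background is one limit, since background left in the values shrinks differences of dim genes. Both normexp corrections left counts of changed genes at 0. Each adds its offset back to every value, and 50 exceeds every array median, so they cannot show whether background hides changes. Normexp ended list calls: extracellular matrix for keratin (adjusted p = 0.0988 at offset 50 and 0.119 at 16) and sebaceous gland for minoxidil (0.0588 at 16) against untreated, oxidative phosphorylation for minoxidil against keratin (0.0782 at 50) and muscle against microsphere keratin (0.0677 at 50).

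The replicate block left all counts of changed genes at 0. Differences between arrays 1 and 2 correlated across genes between every pair of groups, at 0.112 to 0.594, and without minoxidil array 1 the first principal component (59.9% of variance) separated the numbers. With 2 numbers this is only a hint that they mark a shared batch. The block ended 4 list calls: extracellular matrix for keratin (adjusted p = 0.171) and microsphere keratin (0.111) against untreated and for minoxidil against keratin (0.0601), and macrophage for microsphere keratin against untreated (0.0792). It added hair matrix for microsphere keratin against keratin (0.0292) and cell division for minoxidil against microsphere keratin (0.0109). Lists called for microsphere keratin against untreated went from 2 to 0.

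Genes 2-fold apart in both pairs numbered 12 with crossed pairs, 6 at 1.5-fold and 2 after quantile normalization for minoxidil, 1, 28 and 1 for keratin, and 5 at 1.5-fold for microsphere keratin. The correlation of minoxidil with keratin effects became -0.0874 with no filter, 0.0819 after quantile normalization and 0.338 to 0.351 without an untreated array. With microsphere keratin it became -0.0810, 0.120 and 0.371 to 0.374. That between keratin and microsphere keratin became 0.777, 0.764 and 0.812 to 0.923. The cause was not tested.

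Every list call was lost with an estimated correlation (0 lists in each comparison). For minoxidil against untreated, 6 lists became 3 after quantile normalization, 3 with the median filter, 11 with every probeset, 12 without minoxidil array 1 and with the block, and 4 to 13 with 1 array left out. For keratin, 7 became 11 without minoxidil array 1 and untreated array 1, and 1 to 14 with 1 array left out. For microsphere keratin, 2 became 0 after quantile normalization, 0 with array weights, 6 with every probeset, 9 without both doubted arrays and 2 to 9 with 1 array left out. For microsphere keratin against keratin, 6 became 10 with every probeset and 5 to 19 with 1 array left out. For minoxidil against keratin, 6 became 10 with no filter, 10 with the mean of probesets, 13 with every probeset, 14 without minoxidil array 1 and with the block, 17 without both doubted arrays and 6 to 17 with 1 array left out. Against microsphere keratin, 6 became 10 with no filter, 14 with every probeset, 17 without minoxidil array 1 and with the block, 17 without both doubted arrays and 4 to 17 with 1 array left out.

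Some lists turned in direction relative to the other genes. With 1 array left out, mean log2 differences for minoxidil against untreated ran from -0.46 to -0.088 for keratin-associated proteins, -3.43 to 1.41 for muscle, -0.44 to 0.74 for sebaceous gland and -1.93 to 0.70 for oxidative phosphorylation. Without minoxidil array 1 and with the block, muscle was 0.84 and oxidative phosphorylation 0.43. Without both doubted arrays these were 0.24 and 0.087, and keratin-associated proteins 0.035. For keratin against untreated, the ranges were -0.011 to 0.61 for extracellular matrix, 0.072 to 0.73 for macrophage, 0.072 to 0.30 for interferon response, -0.18 to 0.22 for cell division and -0.22 to 0.18 for hair matrix regulators. For microsphere keratin they were 0.073 to 0.64 for extracellular matrix and 0.025 to 0.55 for macrophage. Against keratin they were -0.20 to 0.47 for cell division, -0.44 to 0.21 for macrophage, -0.21 to 0.033 for clock and -0.00048 to 0.21 for melanocyte genes. For minoxidil against keratin, extracellular matrix ran from -1.05 to -0.13 and was 0.067 without minoxidil array 1 and with the block, and oxidative phosphorylation ran from -2.20 to 0.43, at 0.16 with that block and 0.43 without both doubted arrays. Against microsphere keratin, muscle ran from -4.04 to 0.80 (0.23 and 0.80), extracellular matrix from -1.10 to -0.19 (0.013 with the block) and oxidative phosphorylation from -2.23 to 0.40 (0.14 and 0.40).

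Several genes fixed for minoxidil changed sign, though Fgf7 for minoxidil kept its own, at -0.27 to -0.12 with 1 array left out. For minoxidil, Sult1a1 was -0.023 after quantile normalization, -0.014 after median centring, -0.0086 and -0.019 with normexp offsets 50 and 16, and -0.059 to 0.069 with 1 array left out. Vegfa was -0.037 without both doubted arrays and ran from -0.028 to 0.62. Igf1 was -0.038 with the mean of probesets and ran from -0.013 to 0.11. Abcc9 was 0.46 without minoxidil array 1 and with the block, 0.15 without both doubted arrays, and ran from -1.04 to 0.84. For keratin, the ranges were -0.37 to 0.28 for Vegfa, -0.035 to 0.91 for Igf1, -0.0036 to 0.43 for Fgf7 and -0.56 to 0.82 for Abcc9, which was -0.014 after quantile normalization and -0.56 without both doubted arrays. For microsphere keratin, Sult1a1 ran from -0.043 to 1.03, Vegfa from -0.34 to 0.30 (0.018 with normexp offset 16) and Abcc9 from -0.56 to 0.82 (-0.0098 after quantile normalization, -0.56 without both doubted arrays).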

Other observations

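The list of hair-shaft and root-sheath keratins did not move as evenly with keratin treatment as the keratin-associated proteins did. It also holds genes that are not keratins, among them Tchh, Tchhl1, S100a3, Padi3 and Psors1c2, so it does not measure filament proteins alone. The mean of 25 measured members differed from untreated by 0.41 on the log2 scale in the number 1 pair and -0.05 in the number 2 pair (camera adjusted p = 0.200, not called). The difference between the 2 lists was not tested.

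Fbxo32 and Trim63, ubiquitin ligases of muscle protein breakdown, were 11.3-fold and 6.68-fold higher in keratin array 2 than in untreated array 2 in the authors' deposited table, and were chosen after these values were seen. In the value table their log2 differences were 2.19 and 1.90 in the number 2 pair and -0.84 and -0.76 in the number 1 pair. Without minoxidil array 1, 13 lists were called in minoxidil array 2 against untreated, 5 up and 8 down. Brown fat genes (9 members) and cholesterol synthesis genes (20 members) were among those up (adjusted p = 3.7e-04 and 5e-04), beside sebaceous gland, skeletal muscle (1.41) and oxidative phosphorylation (0.70). Untreated array 1 was low for these lists: in the number 2 pair alone brown fat differed by 0.36, cholesterol synthesis by 0.23, muscle by 0.24 and oxidative phosphorylation by 0.09, and the last 2 calls were lost without untreated array 1 as well (adjusted p = 0.165 and 0.385). The brown fat list shares 2 members, Cidea and Elovl3, with the sebaceous list. Ucp1 was not among its measured members, and its means ranked the 8 arrays in the same order as those of skeletal muscle. The brown fat call therefore cannot be told apart from a difference in muscle. Those called down ranked below the other genes rather than lying far below untreated. Among them, keratin-associated proteins had a mean difference of -0.088, dermal papilla -0.00045, endothelium -0.06 and epidermal differentiation 0.03. The macrophage and dendritic list had -0.018 and the wound and stress epidermis list -0.030. Each of these 13 calls was lost with an estimated correlation, at adjusted p from 0.647 to 0.876.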
